A study of Drosophila melanogaster with 4 samples.

How the data were processed

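MBD-R2 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster, 14 to 16 h old. The labels list 2 ChIP libraries, made with an antibody called Q4167, and 2 input libraries, which are sequenced chromatin that was not immunoprecipitated. Each input is described as the background of the ChIP library with the same replicate number. Per the labels' protocols, embryos were fixed with formaldehyde, and chromatin was incubated with antibody and collected on beads before the DNA was extracted.

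Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7. Per the file headers, the positions refer to FlyBase release 5 of the genome, and all coordinates here are on that release, counted from 1. The deposited files are lists of regions of significant enrichment, called clusters here. The lists used here are 1 for each ChIP replicate and 1 combined list for the replicate set. Each cluster carries 1 score, which the authors' caller gave and whose scale and normalization are not given in the sources used here. The caller, its threshold and the rule by which the combined list was made are also not given in the sources used here. The score was therefore used to rank, filter or describe clusters within a list. Between replicates it entered as a rank correlation, as values side by side, and as the mean and SD of each list's median or difference, which takes both lists to share a scale that was not checked. The inputs enter only through the authors' calls. Read depth is unknown from these lists, so no floor for an undetected region is given. A cluster that is missing from 1 list can reflect its depth or threshold.

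The tests in this section were fixed before the data were examined, except where they are named as added. Clusters of different lists were matched when they overlapped by at least 1 bp. The share of matched clusters was compared with 1000 circular shifts of 1 replicate along each sequence, two-sided, which keeps cluster widths and spacing. Intervals on shares of clusters are 95% Wilson intervals and cover counting error only. The covered share of a sequence is the percentage of its bases under clusters. X was compared with the 4 large autosomal arms, 2L, 2R, 3L and 3R, by permuting 500 kb windows between them 100000 times, two-sided. Cluster widths were compared by permuting clusters within each replicate 100000 times. Scores on X, scores and covered shares on chromosome 4, the covered share of heterochromatic (Het) and unplaced (U) scaffolds, gaps between clusters on X and the spread among the 5 large arms were added after the data were seen, with the same permutations. Also added then were the comparison of gaps with 1000 random placements that keep the number and widths of clusters on each arm, the stretches of at least 200 kb without clusters, the Fisher's exact tests of the combined list by chromosome, and the scores on U. The Benjamini-Hochberg adjustment covers the 7 comparisons with the autosomal arms as 1 family and the 3 Fisher's exact tests as another. The test of spread among arms, the tests of gaps against random placement and all tests under alternative settings are unadjusted. Neighbouring clusters and windows are not independent, and the labels do not say whether the 2 replicates came from separate embryo collections. The p-values therefore describe differences along the genome within these 2 libraries. With n = 2 in the ChIP group, no test across replicates was run, and each value is given with the SD of both replicates. Permuting clusters within each replicate counts a region found in both lists once per list, which can make those p-values too small. For widths, scores and gaps, regions joined over both replicates, and 500 kb windows, were therefore also permuted together in both lists, a choice made after the data were seen, with the adjustment over the same 7 comparisons.

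The named regions follow a rule fixed in advance: the 10 highest-scoring and the 5 widest clusters of the combined list. Windows, empty stretches and regions of the replicate lists named beyond it were chosen after their values were seen. The plan also held comparisons of transcription start sites, gene ends, X and chromosome 4 genes, gene lists and promoter motifs. Those 6 results need an annotation and sequence of release 5, and the gene table at hand was of release 6, so they were not analysed here and no gene is named. Alternatives were the 50% of clusters with the highest scores, the combined list in place of the replicates, each replicate alone, a minimum overlap of 50% of the shorter cluster, windows of 200 kb and 1 Mb, clusters per Mb in place of covered share, the 6 arms alone, the partner with the longest overlap for scores, and means in place of medians.

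Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The scripts were tested on simulated lists drawn with the real widths and numbers of clusters. For the overlap between replicates, 90% of the 4441 replicate 1 clusters on X and the large autosomal arms were left in place in 1 simulated list, and the recovered share was 90.0%. With 50% left in place it was 49.1%. The recovered share was corrected for the overlap that randomly shifted clusters gave. The shares of overlapping clusters under Results are not corrected in this way. For covered share, 0 of 50 simulated comparisons passed 0.05 with no difference between X and autosomes, and 49 of 50 did with 1.1 times as many clusters per base on X. Those clusters were placed at random, without the grouping of the real ones, so these numbers do not give the power of the real comparison. The number of clusters on each arm was also set from its length without random spread. The 0 of 50 therefore does not give the error rate of the real comparison. For scores, 3 of 50 comparisons of 3600 simulated clusters passed with no shift, and 50 of 50 did with a shift of 0.3. The compared group held 60 clusters, as chromosome 4 did in replicate 1, and scores were drawn independently in 1 list. These numbers therefore do not give the power or error rate for the smaller score difference of 0.0637 on X. With the same simulated clusters in both lists and no shift, 11 of 50 comparisons passed when the lists were permuted separately and 4 of 50 when they were permuted together.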

Results

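MBD-R2 is a chromatin protein of the fly NSL complex, which also holds the histone acetyltransferase MOF and is known for binding near promoters of active genes. Its binding was mapped in wild-type embryos 14 to 16 h old with 2 ChIP libraries, each set against an input of the same replicate number per the labels. All positions are on FlyBase release 5. Replicate 1 held 4586 clusters covering 15.1 Mb, and replicate 2 held 4789 clusters covering 16.3 Mb. On X, 2L, 2R, 3L, 3R and 4 together, clusters covered 12.3% of the sequence in replicate 1 and 13.3% in replicate 2. The median cluster was 2737 bp wide in replicate 1 and 2834 bp wide in replicate 2, and the narrowest measured 1301 bp in each. The combined list held 6826 clusters, of median width 2304 bp, covering 21.8 Mb.

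The replicate lists address how reproducibly MBD-R2 regions were found. Most MBD-R2 regions were found in both libraries, and nearly all strong ones were. Of the replicate 1 clusters, 4146 of 4586 (90.4%, 95% Wilson interval 89.5 to 91.2%) overlapped a replicate 2 cluster. Of the replicate 2 clusters, 4058 of 4789 (84.7%, 83.7 to 85.7%) overlapped a replicate 1 cluster. Bases under clusters in both replicates summed to 13.7 Mb in 4283 regions, which was 77.6% of the bases covered in either. The mean share of overlapping clusters was 87.6% ± 4.0 (SD of both directions), against 22.4% on average and 34.6% at most in 1000 shifted placements (two-sided permutation p = 0.002, the smallest these shifts can give). Among the highest-scoring 25% of clusters, 99.7% of replicate 1 and 99.9% of replicate 2 were shared. Among the lowest-scoring 25%, 73.1% of replicate 1 and 50.4% of replicate 2 were shared. Unshared clusters were narrow, with medians of 1499 bp in replicate 1 and 1582 bp in replicate 2, against 2934 bp and 3119 bp for shared ones. For scores, each cluster was paired with its best-scoring overlapping partner. The Spearman correlation of the authors' scores was 0.923, the mean of both matching directions. The 95% bootstrap interval, taken over replicate 1 clusters and their replicate 2 partners only, was 0.916 to 0.930. It was computed across clusters, which are not independent replicates.

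The highest-scoring combined-list region found in both replicates lay on 2R from 17387146 to 17391484 in the combined list. Its score was 2.67 in the combined list, 2.87 in replicate 1, where it ranked second, and 2.84 in replicate 2, where it ranked first. A region on X from 5630109 to 5633266 in replicate 1 scored 2.38 there and 2.26 in replicate 2. A region on 2R from 19409524 to 19412957 in replicate 1 scored 2.26 there and 2.21 in replicate 2. On 3R, the region from 2948231 to 2951818 in replicate 1 scored 2.30 there and 2.17 in replicate 2. On 3L, the region from 18664509 to 18668095 scored 2.45 in replicate 1 and 2.06 in replicate 2, where 32 clusters scored higher. On U, the region from 7869574 to 7870912 scored 2.97 in replicate 1 and 2.41 in replicate 2, the largest difference among the shared regions of these 10. Also on U, the region from 7221523 to 7224412 scored 2.46 in replicate 1 and 2.64 in replicate 2, and the region from 9618645 to 9620820 scored 2.23 and 2.13. Regions named by their replicate 1 positions were chosen after their values were seen. Of the 10 highest, 8 in replicate 1 and all 10 in replicate 2 overlapped a cluster of the other replicate. The exceptions in replicate 1 were a 1393 bp cluster on 3L from 24346071 to 24347463, with a score of 2.81, and a 1461 bp cluster on unplaced sequence U from 55472 to 56932, with a score of 2.72.

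The widest cluster of the combined list spanned 27.4 kb on 2L from 11986068 to 12013466. It was a single cluster of 26.9 kb in replicate 1 and of 27.0 kb in replicate 2. A 22.9 kb cluster on 2L from 4961600 to 4984454 was also single in each replicate, at 19.6 kb and 19.1 kb. The other wide clusters of the combined list were split in the replicates. The 27.1 kb cluster on X from 6164508 to 6191656 overlapped 5 clusters of replicate 1 and 3 of replicate 2. On 2R, the 26.2 kb cluster from 19736088 to 19762264 overlapped 3 clusters in each replicate. The 23.7 kb cluster on X from 19524534 to 19548198 overlapped 2 clusters of replicate 1 and 3 of replicate 2. The 5 widest of the combined list scored from 1.13 to 1.46, above its median of 0.503 and below its top score of 3.03. Across all its clusters, width and score had a Spearman correlation of 0.733.

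MBD-R2 clusters were gathered in dense stretches separated by long empty ones. The median gap between neighbouring clusters on X and the large autosomal arms was 6.45 kb in replicate 1 and 5.92 kb in replicate 2. Randomly placed clusters of the same number and width gave medians of 16.1 kb and 15.2 kb (two-sided permutation p = 0.002 for each, the smallest possible with 1000 placements). Gaps of at least 200 kb numbered 64 in replicate 1 and 67 in replicate 2, and random placement gave at most 6. Random placement kept only the number and widths of clusters on each arm, so the test shows uneven spacing and not its cause. Wide regions split into several clusters, as in the replicates above, can also add short gaps. The densest 500 kb window was on 2R from 19500001 to 20000000, where clusters covered 37.3% ± 2.1 (SD, n = 2) of the sequence. Next came 2L from 10000001 to 10500000 at 31.9% ± 1.9, 3R from 1000001 to 1500000 at 28.5% ± 1.4 and X from 1500001 to 2000000 at 27.7% ± 2.1. The emptiest full window was on 2L from 14500001 to 15000000, with 0.141% ± 0.20 covered, and the median window had 11.8%.

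**Figure D1:**
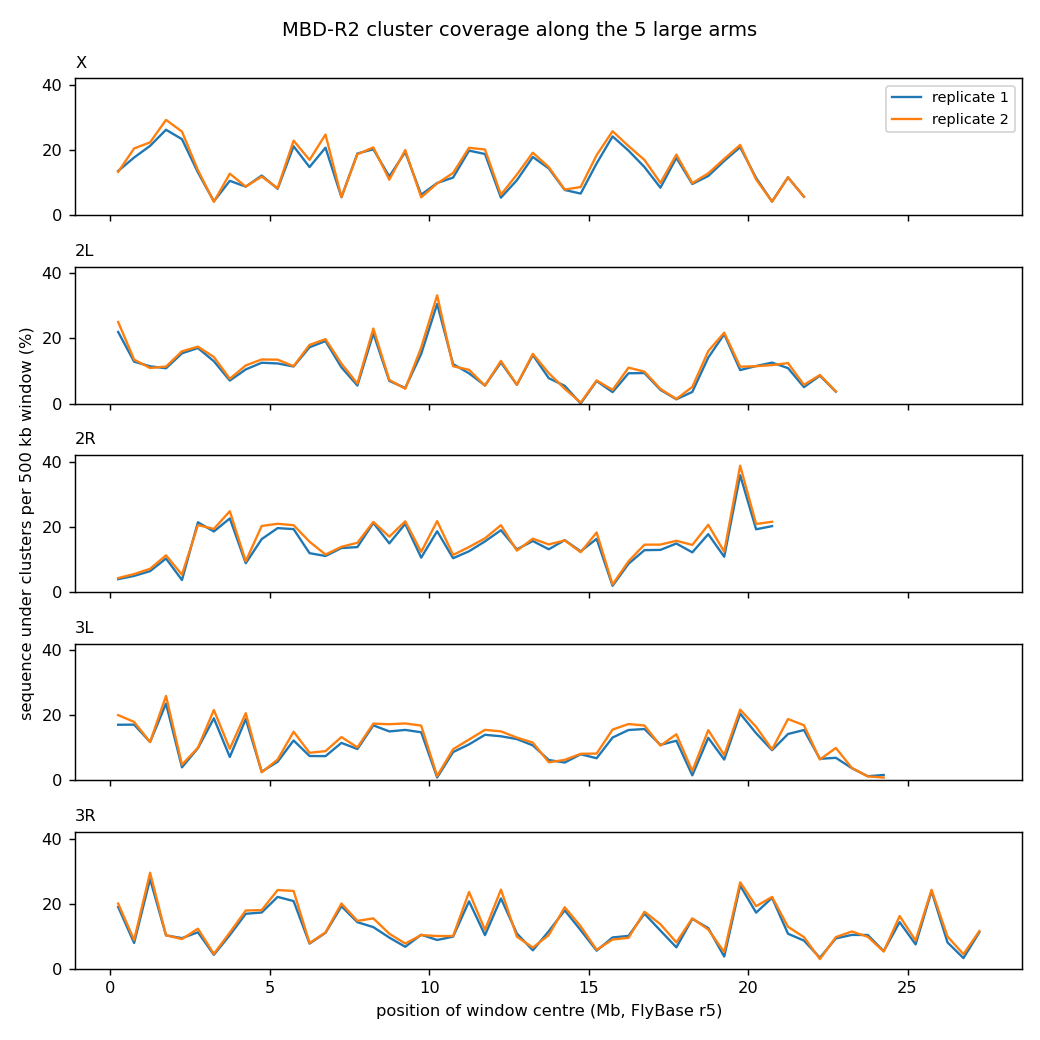
Share of sequence under MBD-R2 clusters (percent) in 500 kb windows along X, 2L, 2R, 3L and 3R, by window centre in Mb, with 1 line per ChIP replicate. The lines run close together in every arm, with the highest peak on 2R at 37.3% (mean of both) and a near-empty window on 2L at 0.141%.

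In all, 52 stretches of at least 200 kb held no cluster in either replicate and summed to 13.4 Mb, or 11.1% of the 6 arms. The longest, of 472 kb, lay on 2L from 16911144 to 17383005, followed by 455 kb on 2L from 14364436 to 14819304. On X, the longest were 374 kb from 21946356 to 22320486 and 363 kb from 7231755 to 7595219. Such stretches made up 16.5% of 2L and 14.2% of X, 11.2% of 3L, 9.07% of 3R and 5.53% of 2R. None lay on chromosome 4. In the combined list, 1 of the 52 stretches held no part of a cluster, the 267 kb on 3R from 23117164 to 23383696. The others were still mostly empty there. Combined-list clusters covered 35 bp of the 472 kb stretch on 2L. The most they covered in any stretch was 11539 bp, in the 455 kb on 2L.

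X was set against the autosomes because MOF, a partner of MBD-R2, also belongs to the MSL complex, which acts on the male X. No comparison by sex was made here, so no result for the male X in particular is given. Clusters covered 14.2% ± 0.64 (SD, n = 2) of X and 12.5% ± 0.71 of the 4 large autosomal arms. The difference of 1.64 ± 0.07 percentage points did not pass the test (permutation of 500 kb windows, p = 0.115, adjusted p = 0.134). The arm with the highest covered share was 2R, at 14.9% ± 0.89, followed by X, 3R at 12.8% ± 0.61, 3L at 11.4% ± 0.88 and 2L at 11.2% ± 0.49. The span of 3.76 percentage points between 2R and 2L passed 0.05 (permutation of windows, p = 0.0274, a test added after the data were seen). It was 5.68 points in the combined list (permutation p = 0.00626). X had 39.9 ± 0.38 clusters per Mb and 2R had 45.8 ± 1.8. The difference between X and the autosomes was 3.09 points in the combined list (permutation p = 0.0232). It was 1.98 points for the 50% of clusters with the highest scores (permutation p = 0.0138). That setting selects on score, which was itself higher on X, so it is not independent of the score difference. Without the 2 Mb at the centromere-side end of each arm sequence, a setting chosen after the data were seen, the difference in covered share was 2.13 points (permutation p = 0.0453). The other settings gave no such result. The difference did not pass with 200 kb windows (permutation p = 0.0852), with 1 Mb windows (permutation p = 0.143), as clusters per Mb (2.10 per Mb, permutation p = 0.452), in replicate 1 alone (1.69 points, permutation p = 0.0911) or in replicate 2 alone (1.59 points, permutation p = 0.141).

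**Figure D2:**
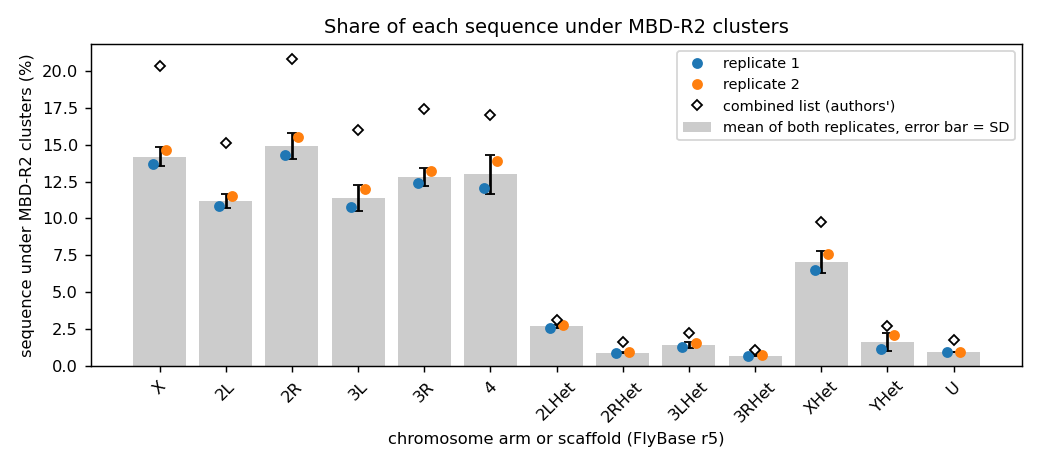
Share of each chromosome arm or scaffold under MBD-R2 clusters (percent of bases, FlyBase r5). Points are the 2 replicates, grey bars their mean with SD, and diamonds the combined list; 2R (14.9%) and X (14.2%) lie highest among the arms, and among Het scaffolds and U, XHet lies highest (7.04%) and 2LHet next (2.68%).

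Clusters on X had higher scores and shorter gaps than those on the 4 large autosomal arms pooled, and the width difference depended on how clusters were permuted. Of the autosomal arms, 3R came close to X in score, at 0.989 ± 0.0048, and in width, at 2880 bp ± 15, while 2R had the lowest score, 0.893 ± 0.0057. The shortest median gap among the autosomal arms was that of 2R, at 6.00 kb ± 0.18. No test of X against single arms was run. The median width was 2943 bp ± 107 (SD, n = 2) on X and 2789 bp ± 55 on the autosomes, a difference of 154 bp (permutation of clusters, p = 0.00402, adjusted p = 0.00563). The median score was 1.00 ± 0.0056 on X and 0.939 ± 0.0081 on the autosomes (permutation p = 0.00097, adjusted p = 0.0017). The median gap was 5.01 kb ± 0.43 on X and 6.54 kb ± 0.37 on the autosomes (permutation p = 8e-05, adjusted p = 0.000187). These permutations count a region found in both replicates once per list. With regions permuted together in both replicates, a test added after the data were seen, adjusted p was 0.0378 for width, 0.0196 for score and 0.00597 for gap. With 500 kb windows permuted together, adjusted p was 0.0879 for width, so that difference did not pass, 0.0448 for score and 0.0324 for gap. The width difference did not pass in replicate 1 alone (117 bp, permutation p = 0.16) and had the opposite sign in the combined list (-136 bp, permutation p = 0.0942). It was 371 bp among the 50% of clusters with the highest scores and 238 bp between means (permutation p = 1e-05 for each, the smallest possible). The score difference was 0.0312 in the combined list (permutation p = 0.0614). The gap difference was -4.03 kb among the 50% of clusters with the highest scores (permutation p = 0.00053). That 50% was selected on score, which was itself higher on X.

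Chromosome 4, a short chromosome rich in repeats, held lower-scoring clusters than the large autosomal arms in each replicate list. Its covered share did not pass a test against those arms. Covered share was 12.98% ± 1.33 (SD, n = 2) on chromosome 4 and 12.5% ± 0.71 on the autosomal arms (permutation of 500 kb windows, p = 0.899, adjusted p = 0.899, with 3 windows on chromosome 4). The median score was 0.642 ± 0.0034 over 60 clusters in replicate 1 and 59 in replicate 2, against 0.939 ± 0.0081 on the autosomal arms (permutation of clusters, p = 1e-05, the smallest possible, adjusted p = 3.5e-05). Adjusted p was 0.00077 with regions, and 0.0324 with 500 kb windows, permuted together in both replicates, tests added after the data were seen. Median widths on chromosome 4 were 2140 bp in replicate 1 and 2312 bp in replicate 2, against 2750 bp and 2828 bp on the autosomal arms, a difference that was not tested. The score difference was 0.00669 in the combined list (permutation p = 0.925) and -0.0460 among the 50% of clusters with the highest scores (permutation p = 0.463). Keeping that 50% selects on the score itself and drops low-scoring clusters, so it cannot tell how firm the score and covered share differences on chromosome 4 are. The covered share difference of 0.456 points was -0.252 points in the combined list (permutation p = 0.956) and -3.06 points among the 50% of clusters with the highest scores (permutation p = 0.263). It was 0.892 points in replicate 2 alone and 0.0210 points in replicate 1 alone.

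Heterochromatic scaffolds and unplaced sequence held few MBD-R2 clusters. Together, without the sequence called Uextra, they were covered to 1.09% ± 0.069 (SD, n = 2), against 12.5% ± 0.71 for the autosomal arms (permutation of windows, p = 1e-05, the smallest possible, adjusted p = 3.5e-05). The difference of -11.4 points was -7.60 points among the 50% of clusters with the highest scores (permutation p = 1e-05). Covered share was 0.919% ± 0.013 on 2RHet, 0.705% ± 0.024 on 3RHet, 1.45% ± 0.20 on 3LHet and 2.68% ± 0.098 on 2LHet. XHet stood higher at 7.04% ± 0.76, with 5 clusters in replicate 1 and 6 in replicate 2 on 0.204 Mb. Uextra, 29.005 Mb of further unplaced sequence, held 0 clusters in each list. With it the covered share was 0.437% ± 0.028, and whether it was searched for clusters is not given in the sources used here. On YHet, replicate 1 had 2 clusters and replicate 2 had 4. Repeated sequence takes up much of these scaffolds, and how reads with several positions were treated is not given in the sources used here.

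The combined list differed from the replicate lists mainly by many narrow, low-scoring clusters. It took in 99.5% of the replicate 1 clusters and 99.7% of the replicate 2 clusters. Of its 6826 clusters, 3745 (54.9%, 95% Wilson interval 53.7 to 56.0%) overlapped clusters of both replicates, 1054 (15.4%) overlapped 1 replicate and 2027 (29.7%) overlapped neither. Clusters supported by both had a median width of 3737 bp and a median score of 0.956. Clusters in neither had a median width of 1265 bp and a median score of 0.374, and they made up 12.6% of the bases of the list. The share found in neither replicate was 32.9% on X and 28.7% on the autosomal arms (Fisher's exact test over clusters, p = 0.00329, adjusted p = 0.00493). It was 16.2% on chromosome 4 (exact p = 0.019, adjusted p = 0.019) and 41.8% on Het scaffolds and U (exact p = 0.000459, adjusted p = 0.00138).

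**Figure D3:**
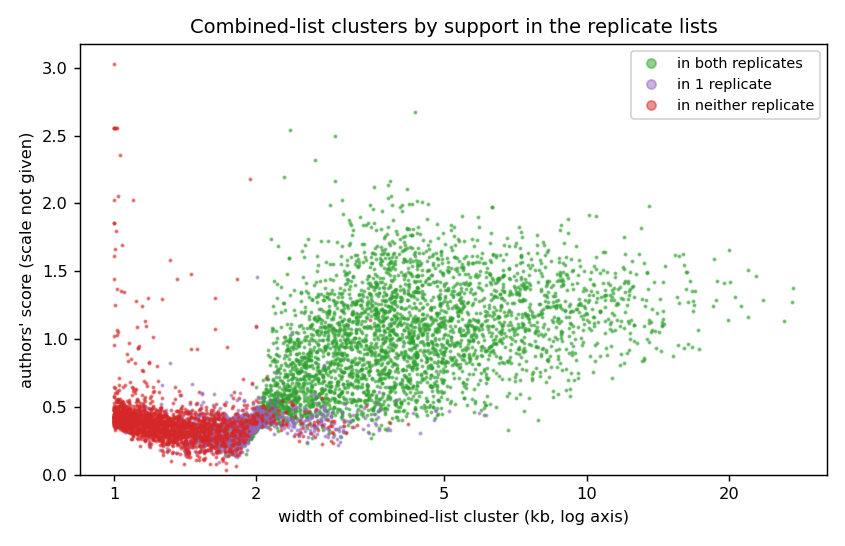
Width (kb, log axis) and the authors' score of each combined-list cluster, coloured by whether it overlapped clusters in both replicates, in 1 or in neither. Clusters in neither replicate gather at narrow widths (median 1265 bp) and low scores (median 0.374), apart from a column of narrow, high-scoring ones near 1 kb.

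Among the 10 highest scores of the combined list, 7 belonged to clusters found in neither replicate. These 7 were between 1001 and 1029 bp wide. The top score of 3.03 was on U from 5426706 to 5427706. A further 5 shared 1 score of 2.56, namely 3R from 3533320 to 3534328, 3R from 26222014 to 26223028, and U from 4066954, 7586688 and 9078544. The remaining one lay on 2R from 6480638 to 6481666, with a score of 2.36. The other 3 of the 10 were present in both replicates: the 2R region at 17387146 and clusters on U from 7869560 to 7871910 (score 2.54) and from 7221518 to 7224456 (score 2.50).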

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

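The tests of the width minimum, of scores without recurring ones, of recurring scores and of unplaced sequence, and all bootstrap intervals, were chosen after the results they bear on were seen. The clusters of the combined list that overlap neither replicate form the first pattern. A lower width minimum in the combined list may be a cause, since 54.1% of them (1096 of 2027) were narrower than the narrowest replicate cluster of 1301 bp. Combined clusters were wider than their one-to-one partners by a median of 358 bp in replicate 1 and 228 bp in replicate 2. The 95th percentile of that excess was 1994 bp in replicate 1. With it added to the 1301 bp minimum, 99.8% of the clusters in neither lay below the sum. So wide a bound could hardly be exceeded by such narrow clusters, so whether the minimum is the whole cause cannot be told. Enrichment too weak to be called in either replicate would leave them with scores at or below those of clusters supported by 1 replicate, but within 100 bp width bins their median score was higher by 0.014 (95% bootstrap interval 0.00111 to 0.0283, two-sided permutation p = 0.0347). Without recurring scores it was higher by 0.0187 (95% bootstrap interval 0.00321 to 0.0349, two-sided permutation p = 0.0354). Of the 1177 combined-list clusters narrower than 1301 bp, however, 1096 were in neither replicate, which leaves few supported clusters of that width for comparison. The differences were also small, and the scale of the score is unknown. Whether weak enrichment is a cause therefore cannot be told, and no biological explanation was tested.

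The second pattern is the narrow clusters with a score over 1.5 that the combined list alone holds, 18 in number with a median width of 1006 bp. Scores estimated from very few reads would take few distinct values, and exact scores (equal to 9 decimals) recurred in 9 of the 18, 5 of which have the shared score among the 10 highest that prompted this test. Without those 10, recurring scores made up 4 of 11 clusters, in 2 pairs that are not independent, and 0 of 350 equally high-scoring clusters supported by both replicates, a difference of 36.4 percentage points (Fisher's exact p = 4.74e-07). Repeated or unplaced sequence, also noticed among the 10 highest, held 7 of the other 11 clusters on U or Het scaffolds against 10 of 350, a difference of 60.8 percentage points (Fisher's exact p = 3.88e-08). Scores recurred in 32.2% of all clusters in neither replicate and in 3.10% of those in both, so recurrence was not particular to the high-scoring ones. The groups were also not matched for width. The difference in recurring scores therefore does not tell why these scores are high. Both explanations stay open and may act together, and no biological explanation was tested.

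The third pattern is the low score of clusters on chromosome 4. Narrower clusters on that chromosome are a candidate explanation, since score rose with width across clusters (Spearman correlation 0.76 in replicate 1 and 0.77 in replicate 2). Within 250 bp width bins the difference shrank from -0.297 to -0.115 ± 0.077 (SD, n = 2). It was -0.060 in replicate 1 (permutation p = 0.0627) and -0.169 in replicate 2 (permutation p = 0.0002), so the replicates do not decide whether width covers all of it. Width and score come from the same calls, so matching on width may also remove part of the score difference itself. The shrinkage therefore does not show that width is a cause. No biological explanation was tested.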

How the results depend on the processing

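No paired analysis was possible because the 2 inputs enter only through the authors' calls and have no values of their own here. The overlap between replicates, their score correlation and the combined list's support need both replicates, so leaving 1 out gives no value for them. The 6 planned results on genes and promoters were not run, for want of a release 5 annotation. Of 54 alternatives to results with a test, 43 kept their direction and side of the threshold. A further 4 concern values without a test, and among these the count of clusters found in the combined list alone fell from 2027 to 1583 when clusters within 1000 bp counted as supported, an alternative chosen after seeing the data. All alternatives for chromosome 4, the Het scaffolds and U, scores and gaps on X, and the spread among arms were chosen after seeing the data. Restricting lists to the 50% of clusters with the highest scores gave a score correlation of 0.845, an X minus autosome covered share of 1.98 points (past 0.05), a chromosome 4 covered share difference of -3.06 points (opposite sign) and a chromosome 4 score difference of -0.0460 (no longer past 0.05). This restriction selects on score, which was higher on X and lower on chromosome 4, so these differences are not independent of it. It also narrows the range of scores, which by itself can lower a correlation. Using the combined list gave 3.09 points for X covered share (past 0.05), -0.252 points for chromosome 4 covered share, -136 bp for X width and 0.00669 for chromosome 4 score, the last 3 with opposite sign, and 0.0312 for X score (no longer past 0.05). Leaving out the 2 Mb at the centromere-side end of each arm sequence, an alternative chosen after seeing the data, gave 2.13 points for X covered share (past 0.05). Leaving out each replicate moved the X width difference between 117 and 191 bp, and it did not pass without replicate 2. With 500 kb windows permuted together in both replicates, chosen after seeing the data, the X width difference of 154 bp no longer passed (permutation p = 0.0628). Leaving out each replicate moved the chromosome 4 covered share difference between 0.0210 and 0.892 points. The cause of these changes was not tested. Depth is unknown, which limits any statement about regions missing from a list.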

Other observations

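All tests of scores on U, of windows at the centromere-side ends of the arm sequences and of gaps on X were chosen after the data were seen. Sequence U, which gathers assembled pieces with no known chromosomal place, entered the comparisons above only together with the Het scaffolds. It held 40 clusters in replicate 1 and 39 in replicate 2. Of these, 32 in each replicate overlapped a cluster of the other. Their median score was 1.27 in replicate 1 and 1.17 in replicate 2. It exceeded that of the autosomal arms by 0.334 in replicate 1 (two-sided permutation p = 0.00034) and by 0.223 in replicate 2 (two-sided permutation p = 0.0642).

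MBD-R2 clusters were sparse at the centromere-side end of the arm sequences of X, 2L, 2R and 3L, but not of 3R. The Het scaffolds are separate sequences and lie outside these ends. On 3RHet, clusters covered 0.705% ± 0.024 (SD, n = 2). In the 500 kb windows that reach into the 2 Mb at that end, clusters covered 3.82% ± 0.38 (SD, n = 2) of 3L against 12.1% ± 0.93 of the rest of that arm. The values were 6.71% ± 0.46 against 15.8% ± 0.94 on 2R, 7.17% ± 0.097 against 15.0% ± 0.73 on X, and 7.30% ± 0.45 against 11.5% ± 0.49 on 2L. On 3R the share at the centromere-side end was higher, at 16.7% ± 0.70 against 12.5% ± 0.60. Over the 5 arms the difference was -5.01 percentage points. Its p was 0.00021 with single 500 kb windows permuted and 0.00091 with the windows rotated along each arm, which keeps neighbours together. Why 3R differs was not tested.

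Gaps between clusters were shorter on X than on the autosomal arms pooled. When X clusters were thinned at random to the autosomal number per Mb, from 888 to 825 in replicate 1 and from 900 to 869 in replicate 2, the median gap rose from 5.31 to 6.18 kb on average in replicate 1 and from 4.70 to 4.92 kb in replicate 2. It stayed below the autosomal 6.81 kb and 6.28 kb in 100% of 1000 thinnings of each replicate, a test whose rule was set before any thinning was run but which leaves out the spread of the gaps themselves. In the test that replaced it after that value was seen, with 500 kb windows resampled on X and on the autosomes, the thinned difference was -0.997 kb (95% bootstrap interval -1.81 to 0.0688 kb, mean of both replicates). The interval includes 0, so the shorter gaps on X were not separated from the higher number of clusters per Mb.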
